A study of Mus musculus with 6 samples.

How the data were processed

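The series measured polyadenylated RNA from hearts of wild-type ICR mice, an outbred stock, at embryonic day 16.5 (E16.5) and embryonic day 18.5 (E18.5), with 3 libraries at each stage that the design text calls biological replicates. Whether a library came from 1 heart or from several, and from which litter, is not given in the sources used here. Per the labels' protocols, messenger RNA was selected with oligo(dT) beads and fragmented. The second strand of the cDNA was marked with dUTP and removed, so the libraries keep strand. The adapters carried unique molecular identifiers (UMIs), and paired-end reads came from an Illumina NovaSeq instrument. The submitters' processing notes list cutadapt 1.9, HISAT2 2.0.4, UMI-tools, StringTie 1.3.4d and the mouse build mm9, without saying what each was used for. Whether duplicate reads were removed by their UMIs, and whether the counting used strand, is not given in the sources used here.

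The authors deposited 1 table of 31529 genes with Ensembl identifiers, which holds an estimated count and an FPKM value for each gene and library. Per the file headers, the estimated counts are counts per gene, written as whole numbers with totals that differ between libraries. In 19 of 19 low values checked, the FPKM implied a smaller number than the listed count, so the counts appear to be estimates rounded up by the authors. They needed no further rounding. The deposited FPKM values are fragments per kilobase of transcript, scaled to the fragments of each library, per the file headers. For 99.7% of the 11385 genes with over 200 counts in every library, the ratio of count to FPKM between libraries lay within 1% of the median ratio, so both columns hold the same quantification. An estimate of this kind can divide reads between near-identical or overlapping genes in a way that differs from library to library. Named genes with a near-identical copy, or with an overlapping gene at a higher level, are therefore uncertain. Whether both stages were quantified in 1 run is not given in the sources used here.

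Gene positions were taken by Ensembl identifier from GENCODE release M21 on GRCm38, which was not the annotation used to make the counts. Of the deposited identifiers, 29874 were in that release. Of these, 25905 had the same span in the deposited table and 611 lay at the same coordinates, so the deposited coordinates belong to another build and none of them is printed. A total of 189 genes shared a symbol with another gene. Such a symbol was kept for the identifier with the most counts.

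Stages were compared with edgeR 4.0.16 in R 4.3.3. The design had foreseen limma on FPKM values unless the table held counts. As it did, the edgeR quasi-likelihood test (glmQLFit and glmQLFTest, two-sided) was the main test, with filterByExpr, TMM scaling and stage as the only term. The filter left 19959 genes. P-values were adjusted over these genes by the Benjamini-Hochberg method, and an adjusted p under 0.05 is called a change. Standard errors (SE) are the absolute log2 change divided by the square root of the F statistic. Expression levels are TMM-scaled CPM (estimated counts scaled to a common library size) with the standard deviation over 3 libraries. Folds against a stage with 0 counts in all its libraries are lower bounds against a floor of 3 counts over that stage, which covers counting error only. The common biological coefficient of variation was 34.3%.

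Gene lists were fixed before the data were examined, as were the comparison, the named genes and most alternatives. There were 28 lists by function and 22 lists of cell type or quality markers with at least 5 tested members, and 5 shorter lists that are given by value. Sets were tested with camera (limma 3.58.1) at a preset correlation of 0.01, again with an estimated correlation, and with fry. Adjustment ran over the function lists and over the cell type and quality lists separately. For each list the members were also adjusted over the list alone.

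The named genes were 13 fixed in advance, up to 10 in each direction by size of change, and for each list up to 4 members with the smallest p. The genes chosen by size had to pass the adjusted threshold, reach a mean FPKM of at least 5 in the higher stage and show no overlap between stages, without predicted names. Only 13 genes qualified, under the 20 that the rule required, so genes were ranked by unadjusted p as the rule provided, and those that fail correction are given as such. The rule's p for list members was worded for limma. The edgeR p was used because edgeR became the main test. The other genes among the 30 called, the genes of the library split and the list members given beyond 4 per list were chosen after their values were seen. Myl4 and Myl7 were named for a test before their own values were seen, when those of Nppa and Sln had been. Some genes that the rule names are not reported here.

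A fit on simulated counts with the real means and library sizes, over 19195 tested genes, recovered 2 of 83 genes changed 1.5-fold, 21 of 58 changed 2-fold and 51 of 59 changed 4-fold, with 6 false calls. Simulated changes of 1.5-fold were therefore mostly missed at this sample size. A simulated list of 40 genes shifted by 0.3 (log2) gave a camera p of 6.96e-07, and 0 of 99 unchanged lists fell under 0.05. The simulated genes varied independently of one another. In the data, the estimated correlation was 0.22 for nuclear oxidative phosphorylation and 0.73 for the tricarboxylic acid cycle list. The simulation therefore cannot show how often camera at the preset correlation calls unchanged lists here.

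The alternatives were DESeq2 1.42.0, DESeq2 size factors within edgeR, no filter and FPKM filters at 1 and 5, and limma on log2(FPKM + 1). For limma these also covered pseudocounts of 0.1 and 0.5, filters, rescaling to TPM, median-ratio and common-sum scaling, quantile normalization, no trend and robust fits, and a replicate block. Each library was also left out in turn. Alternatives chosen after seeing the data were a term for a mitochondrial share of counts above 30%, leaving out genes with a near-identical copy, adding the counts of copies, the position of a left-out library between the stages, and a test of the pathway annotation in the deposited table. A near-identical copy is another gene with a transcript at least 95% identical over at least 50% of the longest transcript (BLAST 2.17.0). Transcript-level tests were not run, since the table holds genes only.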

Results

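Heart transcriptomes were compared between E16.5 and E18.5, 3 libraries at each stage, in a series on metabolism of mouse organs late in gestation. The estimated counts summed to 77237333, 67082123 and 74393635 in E16.5 replicates 1, 2 and 3, and to 71510191, 65225623 and 61443414 in E18.5 replicates 1, 2 and 3. Mitochondrial genes took 41.4%, 19.9% and 35.0% of the counts in E16.5 replicates 1, 2 and 3, and 33.5%, 26.7% and 25.2% in E18.5 replicates 1, 2 and 3. Adult globin genes took 0.762%, 2.87% and 1.43% at E16.5 and 0.835%, 1.79% and 2.30% at E18.5. Xist, the RNA that coats the inactive X chromosome, was at 965 CPM in E16.5 replicate 2, 1353 CPM in E16.5 replicate 3 and 1189 CPM in E18.5 replicate 3, and at or below 14.6 CPM in the other libraries, in which the Y-linked genes were expressed. Correlations of log2 CPM between libraries ran from 0.937 to 0.967. E16.5 replicate 2 correlated at 0.946 and 0.947 with the other E16.5 libraries, and at 0.953 to 0.964 with the E18.5 libraries.

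**Figure D1:**
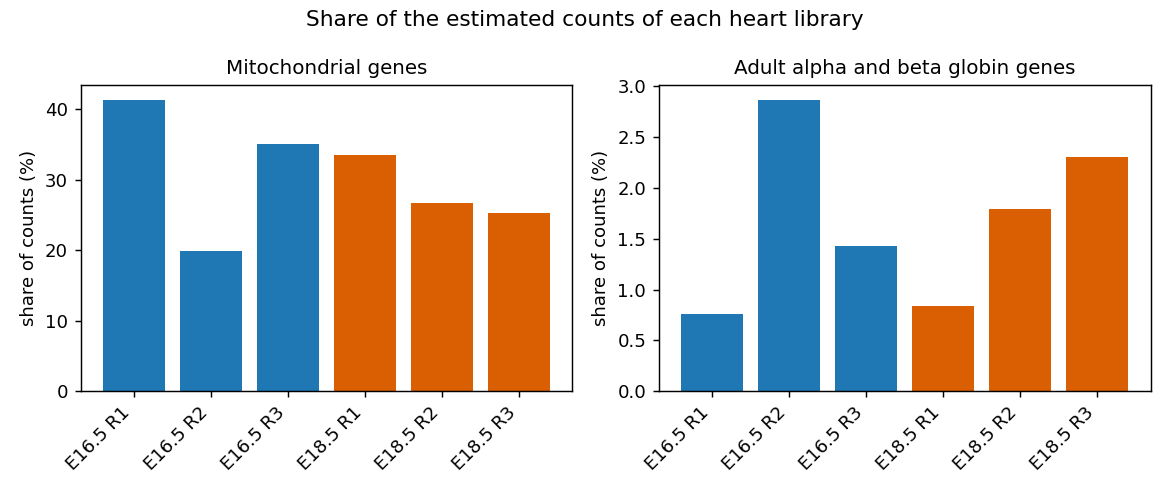
Share of the estimated counts (%) held by mitochondrial genes (left) and by adult alpha and beta globin genes (right), 1 bar per heart library, E16.5 in blue and E18.5 in orange. The mitochondrial share, without copies on chromosome 1, ran from 19.9% to 41.4%, both in E16.5 libraries. It lay above 30% in E16.5 replicates 1 and 3 and in E18.5 replicate 1.

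Between E16.5 and E18.5, single genes of the lipid droplet (Plin4), mitochondrial creatine kinase (Ckmt2), NAD synthesis (Nmrk2), complement (C3) and the epicardium (Krt19) rose in the heart, and those of an embryonic globin (Hbb-y), a glutamine transporter (Slc1a5) and a homeobox factor (Meis2) fell. Crhr2, the receptor for urocortin peptides, rose 3.47-fold, Plin4, a lipid droplet coat protein, rose 5.97-fold, and Nmrk2, a nicotinamide riboside kinase of NAD synthesis, rose 8.57-fold. The embryonic beta-like globin Hbb-y was 10.9-fold lower at E18.5. As sets, genes induced by glucocorticoids, nuclear genes of oxidative phosphorylation and markers of epicardium and atrium were higher at E18.5, and mitotic genes were lower. None of these set calls held with an estimated correlation between genes, where the lowest adjusted p was 0.142 over the function lists and 0.178 over the cell type and quality lists.

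Of 19959 genes tested, 30 changed, 19 higher and 11 lower at E18.5 (edgeR quasi-likelihood, Benjamini-Hochberg). At an unadjusted p under 0.05, 964 genes were higher and 939 lower, where 998 in all would be expected by chance. In each of the 30 genes, the 3 libraries of one stage lay above the 3 of the other, an arrangement that chance gives for 10% of all genes and that selection by the stage test favours. Crhr2 (ENSMUSG00000003476, GRCm38 chromosome 6, 55090049 to 55133016) went from 12.5 ± 0.847 to 43.3 ± 2.17 CPM (SD, n = 3), a log2 change of 1.80 ± 0.13 (SE) with an adjusted p of 0.00338. C3 (ENSMUSG00000024164, chromosome 17, 57203970 to 57228136), the central complement component, went from 7.88 ± 1.64 to 31.9 ± 1.14 CPM, a log2 change of 2.02 ± 0.18 with an adjusted p of 0.00819. Plin4 (ENSMUSG00000002831, chromosome 17, 56100591 to 56109803) went from 9.26 ± 2.73 to 55.2 ± 8.26 CPM, a log2 change of 2.58 ± 0.23 with an adjusted p of 0.00819. Krt19 (ENSMUSG00000020911, chromosome 11, 100140810 to 100148665), a keratin of the epicardium, went from 11.4 ± 0.824 to 26.7 ± 0.666 CPM, a log2 change of 1.23 ± 0.14 with an adjusted p of 0.0219. Ckmt2 (ENSMUSG00000021622, chromosome 13, 91853387 to 91876885), the mitochondrial creatine kinase of striated muscle, went from 11.4 ± 1.35 to 28.0 ± 3.57 CPM, a 2.47-fold rise with an adjusted p of 0.0346. Nmrk2 (ENSMUSG00000004939, chromosome 10, 81198170 to 81202051) went from 1.48 ± 0.560 to 12.7 ± 4.69 CPM, a log2 change of 3.10 ± 0.37 with an adjusted p of 0.0305. Plin4 and Nmrk2 each overlap a gene on the other strand that held more counts, Hdgfl2 at 437% of the level of Plin4 and Atcayos at 515% of that of Nmrk2, and strand use in the counting is not known. The same holds for the list members Tagln (Pcsk7, 186%), Dusp1 (Ergic1, 191%) and Srebf1 (Rai1, 151%).

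Other genes that rose without a near-identical copy were Art3 (log2 change 1.19), Cyp2s1 (1.45), the microfibril gene Mfap5 (1.46), Mcf2l (0.93), the matricellular protein gene Ccn3 (1.81), Fndc1 (2.46-fold higher) and Fmo1 (2.29-fold higher). Their adjusted p ran from 0.0297 to 0.0483. Ahnak2 (1.59) and the noncoding gene ENSMUSG00000121069 (1.17) also rose, but were not in the annotation searched for copies.

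Among genes that fell, Hbb-y (ENSMUSG00000052187, chromosome 7, 103851749 to 103853216) went from 24.5 ± 6.99 to 2.24 ± 1.12 CPM, a log2 change of -3.45 ± 0.38 with an adjusted p of 0.0219. The glutamine transporter Slc1a5 (ENSMUSG00000001918, chromosome 7, 16781340 to 16798274) went from 70.3 ± 6.88 to 35.3 ± 2.00 CPM, a log2 change of -0.99 ± 0.13 with an adjusted p of 0.0398. Meis2 (ENSMUSG00000027210, chromosome 2, 115863064 to 116065839), a homeobox transcription factor, went from 54.3 ± 3.07 to 30.4 ± 0.614 CPM, a log2 change of -0.84 ± 0.11 with an adjusted p of 0.0474. Klhl38 fell by 1.63 on the log2 scale, overlapping Gm15943 on the other strand, and the sum of those 2 genes had a log2 change of -1.80 ± 0.27 with an adjusted p of 0.0657. Genes next in rank by unadjusted p failed the correction. These were Hmgxb3 (log2 change -0.88), the embryonic alpha-like globin Hba-x (-2.65), Fam8a1 (-0.69), Pik3ip1 (-0.73), the proteoglycan Vcan (-0.70), Wdr45 (-0.83), Dhx40 (-0.65) and Txnip (-0.73), with adjusted p from 0.136 to 0.175.

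**Figure D2:**
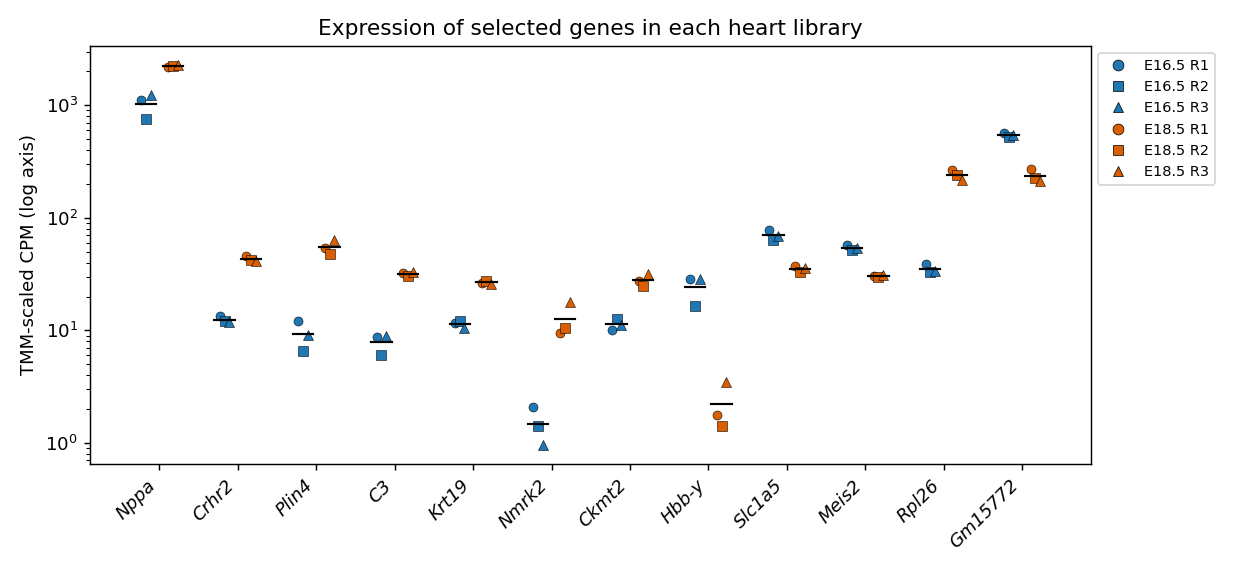
TMM-scaled CPM (log axis) of 12 genes in each heart library, with E16.5 in blue, E18.5 in orange, a marker shape for each replicate number and a black line at the mean of 3 libraries. Crhr2 lay at 11.8 to 13.4 CPM at E16.5 and 41.7 to 45.8 CPM at E18.5, while Rpl26 and Gm15772, whose transcripts are near-identical, moved in opposite directions.

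Of the 30 changed genes, 28 could be searched for near-identical copies and 11 had one, so 17 changes, 13 higher and 4 lower, were free of a copy. The ribosomal protein gene Rpl26 showed a log2 change of 2.77 (35.2 to 240 CPM) and its processed copy Gm15772 one of -1.20 (545 to 237 CPM). The sum of both had a log2 change of -0.28 (adjusted p = 0.570), the opposite direction to Rpl26 alone. Gm20507 had 0 counts in every E16.5 library and was at least 399-fold higher at E18.5, while Pram1, which it overlaps on the same strand, showed a log2 change of -6.24. The sum of Pram1 and Gm20507 differed by 0.0088 (log2). Pcdhga10 had 0 counts in every E18.5 library and was at least 423-fold lower, while its overlapping protocadherin cluster summed to a log2 change of -0.20. At E16.5, Pcdhga10 held 6.34 CPM against 173 CPM for that sum, so the sum cannot show whether its reads moved. The sums of Capza1-ps1 with Capza1 (0.19), of Gm14719 with Ppdpf (-0.18) and of Gm12245, Gm4322 and Bex4 (-0.24) did not pass either. At E16.5, Gm14719 held 5.76 CPM of a sum of 45.52 CPM. Gm12245 and Gm4322 held 2.94 and 3.31 CPM of a sum of 55.25 CPM. Those sums cannot show whether reads moved between the genes. The sum of Gm8113 with its copies did, with a log2 change of 1.26 and an adjusted p of 0.0483.

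None of the 13 genes fixed in advance passed over all genes. The atrial natriuretic peptide gene Nppa was at 1036 ± 248 CPM at E16.5 and 2229 ± 50.6 CPM at E18.5, a log2 change of 1.10 ± 0.20 with an adjusted p of 0.147. With the mitochondrial share of the libraries as a term, its adjusted p was 0.0411. The log2 change was 0.81 (adjusted p = 0.305) for Nppb and -0.55 (adjusted p = 0.432) for the proliferation marker Mki67. It was 0.26 for Myh6 and -0.17 for Myh7, the myosin heavy chains of the adult and fetal mouse ventricle, and 0.33 for Tnni3 and 0.03 for Tnni1, the cardiac and slow skeletal troponin I genes. Genes of fatty acid entry and mitochondrial control gave -0.16 for Cpt1a, -0.16 for Cpt1b, 0.10 for Ppargc1a and -0.11 for Pdk4, and the growth genes gave -0.34 for Igf2 and -0.20 for H19. The last 10 of these genes had adjusted p from 0.569 to 0.974, and the signs of Myh6, Tnni1, Cpt1a, Cpt1b and Pdk4 reversed under at least 1 alternative.

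Metabolic lists moved unevenly. The nuclear subunits of oxidative phosphorylation rose as a set, with a median log2 change of 0.30, 71 of 74 members higher and a camera adjusted p of 8.41e-11 (adjusted p = 0.2497 with an estimated correlation). No member passed over all genes or adjusted over the list alone in edgeR, with 16 higher and 0 lower at an unadjusted p under 0.05, and those with the smallest p were Ndufc2 (0.70), Ndufb10 (0.56), Ndufa11 (0.48) and Ndufb11 (0.55). The median was 0.43 among the 3 libraries with a mitochondrial share above 30% and 0.07 among the other 3. Above 30%, E18.5 replicate 1 is the only E18.5 library, and below it, E16.5 replicate 2 is the only E16.5 library. Each such median, here and for the lists that follow, therefore rests on a single library at 1 of the stages. The list of the tricarboxylic acid cycle and pyruvate dehydrogenase rose with a median of 0.36 and 25 of 27 members higher (adjusted p = 1.02e-06, and adjusted p = 0.477 with an estimated correlation). Its members included Pdhx (0.75), the 1 that rose adjusted over the list alone, with 0 over all genes, and Sdhb (0.42), Dlst (0.36) and Pdk2 (-0.38). Its medians were 0.40 and 0.11 above and below the 30% share, and 0.23 with that share as a term. In its median deviation from the mean of all libraries, E16.5 replicate 2 (0.22) lay above E18.5 replicate 1 (0.014), while the other E16.5 libraries were at -0.38 and -0.41. E16.5 replicate 2 also lay above at least 1 E18.5 library for the fatty acid uptake, extracellular matrix, hypoxia, antioxidant and coronary lists. In fatty acid uptake, storage and PPAR targets (25 genes, median 0.18, adjusted p = 3.69e-04, and adjusted p = 0.254 with an estimated correlation), 4 genes rose and 2 fell adjusted over the list alone, and 1, Plin4, rose over all genes. Plin4, lipoprotein lipase Lpl (0.76), Fabp4 (0.97) and Cd36 (0.65) were those that rose, and Acot2 (-0.91) was among those that fell, with list medians of 0.19 and 0.17 above and below that share. Enzymes of fatty acid oxidation were not called (12 higher and 10 lower, median 0.08, adjusted p = 0.292), with Acadm at 0.24, Acaa2 at 0.57, Eci2 at -0.21 and Crat at 0.25, none of which passed. Their median was 0.18 above the 30% share and -0.17 below it. On the scale of the median log2 change, fatty acid oxidation enzymes were at -0.044 without E16.5 replicate 1. The 13 respiratory subunits encoded in mitochondrial DNA were all lower without passing (median -0.35, adjusted p = 0.0876), at -0.29 and 0.46 above and below that share.

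Both lists of contractile isoforms rose as sets, though the fetal isoforms Myh7 (-0.17) and Tnni1 (0.03) did not pass. Nppa, Myl4, Myl7, Sln and Mybphl of the fetal and atrial list are also atrial markers. The contractile and calcium lists also share members with the cardiomyocyte and smooth muscle markers given below, so a change in cell share is not told apart here. Mature isoforms and structural proteins of the sarcomere had a median of 0.28 with 22 of 27 higher (adjusted p = 2.54e-04, and adjusted p = 0.153 with an estimated correlation). The M-band gene Myom2 (0.92) rose adjusted over the list alone and 0 passed over all genes, beside Tpm1 (0.56), Tnnc1 (0.46) and Lmod2 (-0.41). Fetal and atrial isoforms with the natriuretic peptides had a median of 0.33 with 12 of 16 higher (adjusted p = 2.28e-05, and adjusted p = 0.232 with an estimated correlation). Of these, 6 rose adjusted over the list alone and 0 over all genes, namely Sln (1.16), Tagln (1.40), Nppa, Mybphl (0.80), Nppb and Myl9 (0.53). Calcium handling had a median of 0.14 with 17 of 22 higher (adjusted p = 0.00629, and adjusted p = 0.232 with an estimated correlation). Here 5 rose adjusted over the list alone and 0 over all genes, which were Casq1 (0.77), the ryanodine receptor Ryr2 (0.52), the calcium pump Atp2a2 (0.77), Casq2 (0.48) and Srl (0.65). The medians above and below the 30% mitochondrial share were 0.27 and 0.23 for the mature sarcomere, 0.30 and 0.38 for the fetal and atrial list, and 0.21 and 0.22 for calcium handling.

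Genes of the mitotic cell cycle were lower as a set, with a median of -0.21 and 35 of 40 lower (adjusted p = 2.28e-05, and adjusted p = 0.2497 with an estimated correlation). No member passed over all genes or adjusted over the list alone in edgeR, with 0 higher and 10 lower at an unadjusted p under 0.05, and the smallest p belonged to Cks2 (-0.60), Cenpf (-0.46), Cenpe (-0.59) and Cdca3 (-0.67). The medians above and below the 30% share were -0.28 and -0.19. The 39 genes of DNA replication were not called (adjusted p = 0.556), and their median of 0.03 and mean of -0.02 differed in sign. Cardiac transcription factors had a median of -0.17 with 19 of 29 lower (adjusted p = 0.00629, and adjusted p = 0.2497 with an estimated correlation). Meis2 fell both adjusted over the list alone and over all genes, beside Irx2 (-0.38) and Meis1 (-0.46). The imprinted growth network had a median of -0.18 with 17 of 25 lower (adjusted p = 0.0433, and adjusted p = 0.2497 with an estimated correlation), and 0 members passed over all genes or adjusted over the list alone. Peg10 was at -0.71, Plagl1 at -0.45, Igf2r at -0.36 and Ppp1r9a at -0.54. The medians above and below the 30% share were -0.18 and -0.08 for transcription factors and -0.14 and -0.29 for imprinted genes.

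Genes induced by glucocorticoids rose as a set, with a median of 0.46, 17 of 20 higher and an adjusted p of 4.43e-08 (adjusted p = 0.142 with an estimated correlation). Of these, 7 rose adjusted over the list alone and 0 over all genes. The kinase Sgk1 (2.30-fold higher, adjusted p = 0.0525 over all genes), the transcription factors Zbtb16 (2.18), Klf9 (1.09) and Cebpd (0.77), the chaperone partner Fkbp5 (0.87), Lcn2 (1.18) and Dusp1 (0.45) were the 7. The median was 0.45 above and 0.39 below the 30% mitochondrial share. Dusp1 is also in the quality list of immediate early and dissociation response genes, which rose as a set (median 0.35, adjusted p = 0.270 with an estimated correlation). Smaller set calls were hypoxia-induced genes (17 of 20 higher, median 0.24, adjusted p = 3.55e-04), antioxidant defence (21 of 25 higher, median 0.21, adjusted p = 0.00193) and synthesis of fatty acids and glycerolipids (19 of 22 higher, median 0.21, adjusted p = 0.00438). Their adjusted p with an estimated correlation was 0.310, 0.497 and 0.244. Adjusted over the list alone, 3 hypoxia genes rose, P4ha2 (0.65), Higd1a (0.75) and Vegfa (0.66), and 2 synthesis genes rose, Mlxipl (0.93) and Srebf1 (0.50), with 0 antioxidant genes and 0 of the 3 lists' members over all genes. Medians above and below the 30% share were 0.22 and 0.11 for hypoxia-induced, 0.27 and -0.04 for antioxidant and 0.17 and 0.07 for synthesis genes.

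**Figure D3:**
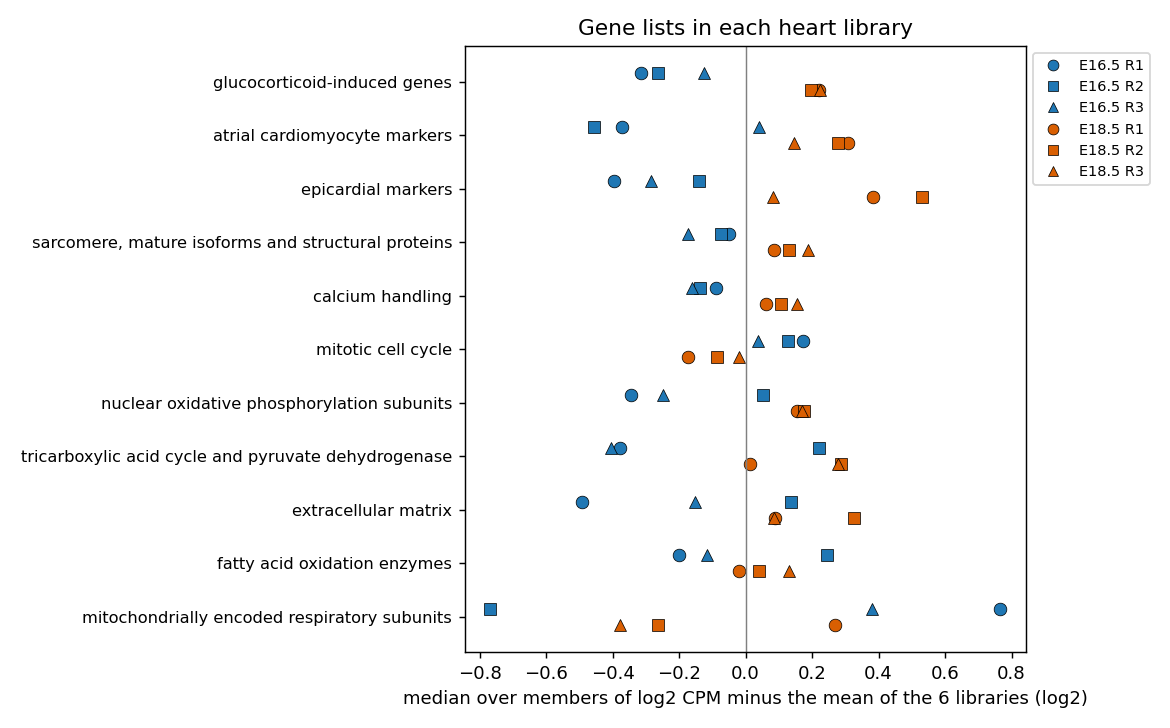
Median over the members of each gene list of log2 CPM minus the mean of the 6 libraries, 1 point per heart library, with E16.5 in blue, E18.5 in orange and a marker shape for each replicate number. For the glucocorticoid-induced genes the E16.5 libraries lay from -0.32 to -0.12 and the E18.5 libraries from 0.20 to 0.22, while for nuclear oxidative phosphorylation subunits E16.5 replicate 2 lay at 0.05, apart from -0.34 and -0.25 in the other E16.5 libraries.

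Markers of several cell types differed between the stages. Epicardial markers had a median of 0.68 with 11 of 12 higher (adjusted p = 6.89e-10, and adjusted p = 0.178 with an estimated correlation). Krt19 rose over all genes, and 6 rose adjusted over the list alone, Krt19, mesothelin Msln (1.13), Upk1b (1.06), Lrrn4 (1.58), Krt7 (0.76) and Krt8 (0.78). Atrial markers had a median of 0.54 with 9 of 11 higher (adjusted p = 2.64e-07, and adjusted p = 0.178 with an estimated correlation), and 6 rose adjusted over the list alone, Sln, Nppa, Bmp10 (0.88), Mybphl, Dkk3 (0.54) and Clu (0.65), with 0 over all genes. Fibroblast markers (11 of 12 higher, median 0.38, adjusted p = 4.18e-04, and adjusted p = 0.270 with an estimated correlation) included Ogn (1.12) and Dpt (0.63), the 2 that rose adjusted over the list alone. The extracellular matrix list had a median of 0.33 with 37 of 45 higher (adjusted p = 1.89e-06, and adjusted p = 0.477 with an estimated correlation). In it Mfap5 and Col6a3 (0.95) rose and Vcan fell adjusted over the list alone, and 1, Mfap5, rose over all genes, beside Lox (0.88). Medians above and below the 30% share were 0.86 and 0.37 for epicardial, 0.53 and 0.64 for atrial, 0.71 and 0.13 for fibroblast, and 0.42 and 0.04 for matrix genes.

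Coronary endothelial markers (11 of 13 higher, median 0.42, adjusted p = 0.00186, and adjusted p = 0.440 with an estimated correlation) and smooth muscle and pericyte markers (10 of 12 higher, median 0.36, adjusted p = 8.49e-04, and adjusted p = 0.178 with an estimated correlation) also rose as sets. Adjusted over the list alone, Fabp4 rose in the first and Tagln and Myh11 (1.79) in the second, with 0 over all genes in either. The general cardiomyocyte markers had a median of 0.26 with 10 of 12 higher (adjusted p = 0.0207, and adjusted p = 0.221 with an estimated correlation), and the quality list of immediate early and dissociation response genes had a median of 0.35 with 14 of 19 higher (adjusted p = 0.00238, and adjusted p = 0.270 with an estimated correlation). Neither list had a member that passed over all genes or adjusted over the list alone. Endocardial markers were lower in 8 of 8 genes (median -0.40, adjusted p = 0.00186, and adjusted p = 0.440 with an estimated correlation), though their median was 0.015 in the limma fit on values rescaled to TPM, where the median of all genes was 0.147. Among endocardial markers E16.5 replicate 1 (median deviation -0.21) lay below 2 of the E18.5 libraries. Lower were also cartilage markers, in 6 of 8 (median -0.65, adjusted p = 4.18e-04, and adjusted p = 0.178 with an estimated correlation). Adjusted over the list alone, Tmem108 (-0.92) and Adgrg6 (-0.89, with Gm10335 on the other strand at 626% of its level) fell in the first and Col2a1 (-1.90) and Col9a2 (-0.97) in the second, with 0 over all genes. Coronary markers were at 0.54 above and -0.05 below the 30% share, endocardial markers at -0.10 and -0.79, smooth muscle markers at 0.29 and 0.20, cardiomyocyte markers at 0.25 and 0.29, cartilage markers at -0.41 and -0.47, and immediate early genes at 0.26 and 0.24. At the preset correlation, calls of the imprinted, endocardial, coronary, immediate early, cardiomyocyte and transcription factor lists were lost under some alternatives, and that of the antioxidant list without E16.5 replicate 1.

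The other cell type and quality lists did not pass. Their median log2 changes were -0.07 for ventricular cardiomyocytes, 0.17 for endothelium, 0.14 for lymphatic endothelium, 0.11 for valve cells, -0.05 for macrophages, 0.0056 for other myeloid cells, -0.19 for erythroid cells and 0.29 for platelets. They were 0.59 for Schwann cells and neurons, -0.08 for skeletal muscle, -0.06 for lung epithelium, -0.11 for hepatocytes and 0.10 for heat shock genes. The mean or the test had the opposite sign to the median for valve, macrophage and hepatocyte markers. Of the function lists that did not pass, the medians were 0.21 for glycolysis and glucose transport, 0.17 for glycogen, 0.33 for ketone bodies and 0.15 for branched chain amino acids. They were 0.08 for nucleotides, 0.06 for serine and one-carbon metabolism, 0.14 for cholesterol synthesis and 0.04 for ion channels. They were 0.10 for mitochondrial regulators, -0.15 for Igf and insulin signalling and -0.10 for cytosolic ribosomal proteins. In them Slc1a5 fell in the serine list and Rpl26 was higher among ribosomal proteins, each over all genes and adjusted over the list alone, but the sum of Rpl26 with Gm15772 was not (-0.28). Among lists given by value, the median was -2.95 for the 3 primitive globins, -0.70 for the 4 lymphocyte genes tested, 0.85 for the 2 adipocyte genes tested, 0.97 for Y-linked genes and -0.95 for Xist. High Xist was found in E16.5 replicates 2 and 3 and in E18.5 replicate 3. The Y-linked and Xist values therefore follow an uneven mix of Xist-expressing and Y-expressing libraries between the stages. No fit had a term for sex.

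Counts of changed genes depended on the tool and on single libraries. DESeq2 called 204 genes higher and 139 lower, including the 30, and limma on FPKM rescaled to TPM called 5 and 5. Leaving out E16.5 replicate 2 gave 371 calls, including the 30, where leaving out any 1 of the other libraries gave 8 to 16. The stage given for E16.5 replicate 2 was checked only by its expression at the genes called without it, given below, which leaves it open. Of the 30, 7 stayed called whichever library was left out (Rpl26, Crhr2, C3, Gm8113, Gm20507, Gm4322 and Pcdhga10), and Plin4 was lost only without E16.5 replicate 3. Of these 7, sums with copies or overlapping genes did not pass for Rpl26 (-0.29), Gm20507 (-0.18), Gm4322 (-0.24) and Pcdhga10 (-0.20). That of Gm8113 (1.26) did. Other genes held most of the counts in the sums of Gm20507, Gm4322 and Pcdhga10, so those sums cannot show whether reads moved between genes. Nmrk2 and Hbb-y were called in 2 of the 6 fits that leave out a library. Krt19, Ckmt2, Slc1a5 and Meis2 were called in 1, the fit without E16.5 replicate 2. Adding the mitochondrial share as a term gave 46 higher and 16 lower, including the 30.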

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

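The mitochondrial share term, the removal of genes with near-identical copies and the summing of copies were chosen after seeing the data. So were the position of a left-out library and the test of the pathway annotation. The other alternatives were chosen before. None of the 30 called genes changed sign when 1 library was left out. The genes higher at E18.5 and the genes lower at E18.5, 19 and 11 in the edgeR fit, numbered 204 and 139 with DESeq2, and 3 and 2 in edgeR at a mean FPKM of at least 5. With limma they were 4 and 4 on log2(FPKM + 1), 5 and 5 at pseudocount 0.1, 5 and 4 at pseudocount 0.5, 1 and 2 without a filter and 1 and 2 at a mean FPKM of at least 5. Limma gave 5 and 5 after rescaling to TPM, 11 and 5 with median-ratio scaling, 10 and 5 with a common sum, 12 and 6 with quantile normalization, 4 and 4 without a trend and 4 and 4 with robust fitting. The median log2 change of all genes was -0.00193 in the edgeR fit. It was 0.0927 with limma on log2(FPKM + 1), 0.147 after rescaling to TPM, 0.121 and 0.108 at pseudocounts of 0.1 and 0.5, and 0.118 with the limma filter at 5. The mitochondrial share term gave 46 higher and 16 lower genes. Of the 19 and 11 genes, 13 and 4 had no near-identical copy. Without 1 library, 6 to 250 genes were higher and 2 to 121 lower, both highest without E16.5 replicate 2. At the 371 genes called without that library, it lay nearer to the mean of the E18.5 libraries in 247 and nearer to that of the other E16.5 libraries in 124. It lay beyond all 3 E18.5 libraries on the E16.5 side in 211 of them (56.9%), where a library of the E18.5 stage would by chance do so in 25%, before allowing for the choice of these genes without it. Every other library, left out in turn, lay beyond the other stage at 84.6% to 100% of the 8 to 16 genes called without it. Those libraries were nearer to their own stage at 62.5% to 100% of such genes, against 33.4% for E16.5 replicate 2. At Crhr2, C3 and Hbb-y, all called without it, E16.5 replicate 2 was at 12.2, 5.99 and 16.4 CPM. There the E18.5 libraries ran from 41.7 to 45.8, 30.7 to 32.8 and 1.42 to 3.51 CPM. These genes were picked after their values were seen, from those also called with E16.5 replicate 2 as an E16.5 library. They therefore cannot test its stage label. The 211 genes beyond the E18.5 libraries and the 247 nearer to their mean point in opposite directions. A wrong stage label and another embryo age both stay open, so the stage contrast carries that doubt. The cause was not tested.

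Of 14 function lists called, 0 were called with an estimated correlation, with or without the mitochondrial share term, and 9 with fry. Leaving out 1 library gave 13 to 20 function lists and 8 to 10 cell type and quality lists. Of 9 cell type and quality lists called, 0 were called with an estimated correlation, with or without that term, and 3 with fry. Limma called 5 on log2(FPKM + 1), at pseudocounts 0.1 and 0.5, at a mean FPKM of at least 5, with quantile normalization, without a trend and with robust fitting. With an estimated correlation the call ended for the mitotic cell cycle (median -0.21, or -0.22 with the term), for nuclear oxidative phosphorylation subunits (0.30, or 0.26) and for glucocorticoid-induced genes (0.46, or 0.40). These 3 lists otherwise kept their calls, except that the oxidative phosphorylation subunits (0.30) had an adjusted p of 0.0978 with fry. The imprinted list had an adjusted p from 0.0501 to 0.105 in the 16 fits in which its call was lost at a preset correlation.

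Of the log2 changes of named genes under alternatives, 2432 kept direction and call, 143 lost a call, 84 gained one and 20 changed sign. Of all values that changed sign, those of Rpl26 and the endocardial list had been called. The endocardial median was 0.015 after rescaling to TPM, where the median of all genes was higher. On the scale of the median log2 change, fatty acid oxidation enzymes were at -0.044 without E16.5 replicate 1 and -0.0098 with the mitochondrial share term at either correlation. Rpl26 was at -0.29 with its copies added. Myh6 was at -0.016 and Tnni1 at -0.043 with quantile normalization. Tnni1 was at -0.14 with the mitochondrial share term and ran from -0.12 to 0.37 over fits without 1 library. Cpt1a was at 0.0016 and Cpt1b at 0.00033 after rescaling to TPM, and Cpt1a ran from -0.25 to 0.018 over fits without 1 library, highest without E16.5 replicate 2. Pdk4 was at 0.019 with limma on log2(FPKM + 1), without a filter, without a trend and with robust fitting, at 0.060 and 0.037 with pseudocounts of 0.1 and 0.5, and at 0.068 after rescaling to TPM. Over fits without 1 library Pdk4 ran from -0.36 to 0.29, highest without E16.5 replicate 2, and was at 0.028 without E18.5 replicate 1. The cause was not tested.

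The replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at 0.102, 0.185 and -0.0663, and E16.5 replicate 3 correlated best with E18.5 replicate 1 (0.164). With the replicate number as a block, edgeR called 30 genes higher and 13 lower and limma 27 and 8, and edgeR called 16 function and 9 cell type or quality lists, limma 14 and 5. The Pdk4 value was 0.019 in the limma fit with the block. Transcript-level results were not run, since the table holds genes only.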

Other observations

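Tests chosen only after the result was seen were 3 tests of displacement by mitochondrial reads, the sum of Rpl26 and Gm15772, the cardiomyocyte share, the final form of the atrial test, the count of splits for genes and the pathway test. Several genes of lists that did not pass as sets passed only adjusted over the list alone, with an adjusted p of 0.113 to 0.415 over all genes (edgeR quasi-likelihood, n = 3 libraries a stage). Among ion channels, the channel partner Kcnip2 showed a log2 change of 0.97, while the calcium channel gene Cacna1d, which Dcp1a overlaps on the other strand at 103% of its level, was at -0.53. Among Igf and insulin genes, the binding proteins Igfbp7 (1.38) and Igfbp6 (1.38) were higher and the insulin receptor substrate Irs2 (-0.60) was lower. Among ketone body genes, Bdh1 (0.76) and Oxct1 (0.55), which use ketones, were higher. Pparg (1.41), the cholesterol synthesis gene Msmo1 (0.90) and Lyve1 (0.88), a lymphatic and macrophage marker, were also higher.

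Of 313 pathways annotated in the deposited table with 10 to 300 tested genes, 10 passed camera at the preset correlation and 0 with an estimated one, where the lowest adjusted p was 0.884. Oxidative phosphorylation led, with 129 genes, a median of 0.27 and an adjusted p of 4.90e-06. The cell cycle pathway (149 genes, median 0.013, adjusted p = 0.801) did not share the fall of the fixed mitotic list.

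The 6 libraries form 10 splits into 3 and 3, too few for a share under 0.05. Counting the real split, 2 of the 10 gave at least as many genes as the stages (30, highest other 928), 2 gave at least as many function lists (14, highest other 14), and 1 gave as many cell type and quality lists (9, highest other 7). The split with 928 genes follows the mitochondrial share and so points to a structure of the libraries besides stage. The split with 14 function lists sets E16.5 replicates 1 and 3 and E18.5 replicate 2 against the rest. With E18.5 replicate 1 or 3 in place of E18.5 replicate 2, 13 or 12 function lists were called. The remaining splits that mix the stages gave 1 to 4. The number of function lists called thus followed E16.5 replicates 1 and 3 about as well as it followed stage.

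The first pattern is that split: E16.5 replicates 1 and 3 and E18.5 replicate 1 (mitochondrial share above 30%) against the other 3 libraries gave 519 genes higher and 409 lower, among them Micu3 at 2.83, Hbb-bs at -2.67, Hbb-bt at -2.33, Alas2 at -1.41 and Ldha at -1.33 (log2). Displacement of other reads by mitochondrial reads would lower all nuclear genes alike, which scaling takes out. Leaving mitochondrial genes out before scaling changed almost nothing (906 genes called against 907 nuclear genes, 894 shared). Scaling had already taken out an equal shift, so this outcome was set in advance whatever the cause and decides nothing. The other 2 of the 3 tests decide nothing either, so displacement stays open. The 54.9% higher among genes called after scaling restate the direction of those calls. The 4.72% higher of 3201 nuclear genes called without scaling factors restate the grouping by mitochondrial share. Transcript length is argued against as the cause, with a Spearman correlation across genes of -0.0564 between exon length and the log2 difference, genes not being independent replicates, while GC content stays open, since its correlation of 0.147 lies between the bounds set for either outcome. Erythroid markers were lower in the libraries above 30% (median -0.37, camera adjusted p = 6.71e-11, and adjusted p = 0.288 with an estimated correlation), as were lists that also differed between stages, such as the tricarboxylic acid cycle (-0.50), extracellular matrix (-0.36), antioxidant defence (-0.36), hypoxia (-0.28), nuclear oxidative phosphorylation (-0.25), coronary endothelium (-0.49) and fibroblasts (-0.28), with adjusted p from 0.428 to 0.764 with an estimated correlation, so blood content, dissection, RNA handling and embryo maturity stay open.

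The second pattern is the group of genes near on or off levels in one stage. Reads shared with near-identical copies are a candidate explanation: 39.3% of the changed genes searched had such a copy against 11.6% of 560 genes matched on expression (Fisher's exact test, two-sided, p = 2.88e-04). That p is too small, since some changed genes are copies of each other and were counted separately. These are Rpl26 with Gm15772, Gm12245 with Gm4322, and Pram1 with Gm20507. The test also took in all changed genes searched, not only those near on or off levels. Some partners counted as copies overlap the gene itself, namely Gm15943 with Klhl38, Gm26672 with Pcdhga10 and Gm20507 with Pram1. The 39.3% therefore covers overlapping genes as well as copies elsewhere. For Rpl26 and Gm15772, the log2 change of their sum, -0.28, is in line with reads moving between both genes rather than with a rise in Rpl26 messenger RNA. A stage difference in which copy is transcribed stays open, as does a separate quantification of each stage, which could divide reads by stage and would be confounded with every stage contrast, overlapped genes such as Plin4 and Nmrk2 included. Genes without a copy, such as Crhr2 and C3, are outside this explanation.

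The third pattern is the movement of cell type markers. A lower cardiomyocyte share at E18.5 as the whole cause is argued against, because other types moved apart, from -0.40 for endocardium to 0.68 for epicardium. The cardiomyocyte markers had a median of 0.26, but most of them are also in the mature sarcomere or calcium lists. Higher expression in each cell could lift that median, so a lower share beside other changes stays open. More atrial tissue in the E18.5 libraries stays open. The abundant atrial transcripts Myl4 (0.20), Myl7 (0.48), Nppa (1.10) and Sln (1.16) showed unequal log2 changes, with a ratio of lowest to highest of 0.169, but Myl4 was at 475 CPM at E16.5 against 30.6 CPM for Sln, and such a level in other cells could hide an added share, although Nppa changed more than Myl4 from a higher level (1036 CPM). Stage-dependent expression within atrial or epicardial cells also stays open and was not tested.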
